A study of Fusarium mangiferae with 30 samples.

How the data were processed

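Total RNA of germinating conidia of Fusarium mangiferae strain MRC7560 was made into QuantSeq 3′ mRNA libraries and sequenced on a NextSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC, STAR 2.5, HTSeq and DESeq2 1.3.4 without saying which step each served. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads shared between near-identical or overlapping genes could not be examined. The deposited values are a signal per gene and library, named normalized counts in the deposited tables, with one table for 8 h and one for 14 h. In every column 100% of the values are whole multiples, within 0.1 read, of one step, as for read counts of the authors divided by one factor per library, so the reads behind each value could be recovered. The tables were scaled separately and are tested separately. They hold 15805 genes with a deposited description, of which 6581 are 0, 3898 read uncharacterized protein and 5299 are informative. Of the locus tags, 15796 are in the RefSeq gene table of the species, which was not used for names or positions.

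Groups are the age, dose and recovery time in the labels. Replicates 2 and 3 of the 8 h group given 200 J/m2 are identical in every value and were used as 1 sample, which leaves n = 2. Depth is the sum of recovered reads, 254400 to 1066826 at 8 h and 3264116 to 6388960 at 14 h. At 8 h, low counts limit what can be detected in genes of low expression.

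Values were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(value + 1), for genes with a value of at least 10 in at least 3 libraries of the table. This left 5371 genes at 8 h, 8947 at 14 h and 5240 in both. Fold changes on this scale understate the changes of low genes. All groups of a table share one estimate of the spread, with 5 residual degrees of freedom at 8 h and 14 at 14 h (prior degrees of freedom 6.25 and 6.2). The age comparison is the difference of the fold changes within each table, with 19 residual degrees of freedom and a shared spread. Tests are two-sided, and p was adjusted by Benjamini-Hochberg per comparison with a threshold of 0.05. The comparisons are each irradiated group against untreated conidia of its age, 200 against 50 J/m2 at each time, successive recovery times within each dose, and 14 against 8 h at 30 min, 18 in all.

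Before the data were examined, 30 gene lists were fixed as patterns on the deposited descriptions, for DNA repair, checkpoints, replication, cell division, ribosomes and translation, protein turnover, stress defence, energy metabolism, growth, secondary metabolism, light response, transport and spore state. Reading the matched names removed 105 members that were other proteins, and 5 lists kept fewer than 4 members. After the descriptions were read, 2 lists were added, the repair genes under other names (25 genes, among them the 70 and 80 kDa subunits of DNA helicase II, called Ku70 and Ku80 in the report, and photolyases) and the mitochondrial ribosomal proteins (34 genes). Lists with at least 4 tested genes, 25 at 8 h and 26 at 14 h, were tested with camera at a preset correlation of 0.01, against all other genes, with p adjusted over the 463 tests. Each list call of the report is also given with the correlation estimated from the data, under which camera called 0 of the 463 tests, against 145 with the preset value. Members are counted with p adjusted over all genes and over the list alone.

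Genes were named by a rule fixed before the data were examined. For each comparison with untreated conidia it takes the 6 largest rises and falls among called genes with an informative name, a mean of at least 20 in the higher group and all irradiated libraries on one side of all untreated ones, for the other comparisons the 4 largest each way, and in each described list the up to 3 members of smallest adjusted p. Members already named may be followed in the dose, time and age comparisons.

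The scripts were tested on simulated counts with the means, spread and depth of the real libraries and 50 genes changed at each of 4 fold sizes. For 50 J/m2 at 30 min and 8 h (4789 simulated genes), limma recovered 0.0% of genes raised 2-fold and 32.0% of those raised 4-fold, and for the same comparison at 14 h (8388 simulated genes) 48.0% and 96.0%. It called 0.00% and 0.10% of unchanged genes. Raising the ribosome biogenesis list 2-fold gave a camera call in both.

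The alternatives tried were pseudocounts of 0.5 and 5, no low-value filter, libraries rescaled to the same total or with TMM factors, the replicate number as a block, only the groups compared in the fit, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads, camera with an estimated correlation, fry, each library left out in turn and, chosen after the data were examined, the 2 libraries of the 14 h table that stand apart left out together. Tables were prepared with Python 3.11.15 and pandas 2.3.3.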

Results

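Gene expression was measured in germinating conidia of the plant pathogen Fusarium mangiferae, strain MRC7560, to follow its response to germicidal ultraviolet light (UVC) over time. The assay was QuantSeq, which reads the 3′ ends of mRNA. Conidia had grown in potato dextrose broth for 8 or 14 h. At 8 h they were left untreated or received 50 or 200 J/m2 and recovered for 30 min. At 14 h they were left untreated or received either dose and recovered for 0, 30 or 60 min. That makes 10 groups of 3 biological replicates and 30 samples, 9 at 8 h and 21 at 14 h. Replicates 2 and 3 of the 8 h group given 200 J/m2 carried the same value for every gene and were counted as 1 sample. This leaves 29 samples and n = 2 in that group. Libraries held 254400 to 1066826 reads at 8 h and 3264116 to 6388960 at 14 h, which limits detection at 8 h. Conidia were filtered out of the culture before irradiation. No untreated group is known to have been handled that way or followed over recovery. Comparisons with untreated conidia may thus cover handling and elapsed time as well as UVC. At 14 h, untreated replicate 3 and replicate 1 of the 50 J/m2 group at 30 min stood apart from their groups, with 601 and 513 genes at least 4-fold from the mean of the group’s other libraries, against 11 to 131 in every other 14 h library. The 2 ages were scaled separately, and no level is compared across them. Paired values are for 50, then 200 J/m2. Fold changes are log2 fold changes with standard errors, group values are mean ± SD of normalized counts, and gene names are the deposited descriptions. Counts given over the list alone have p adjusted within that list. Where a list call starts or ends under another setting or without some libraries, its adjusted p there is given.

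**Figure D1:**
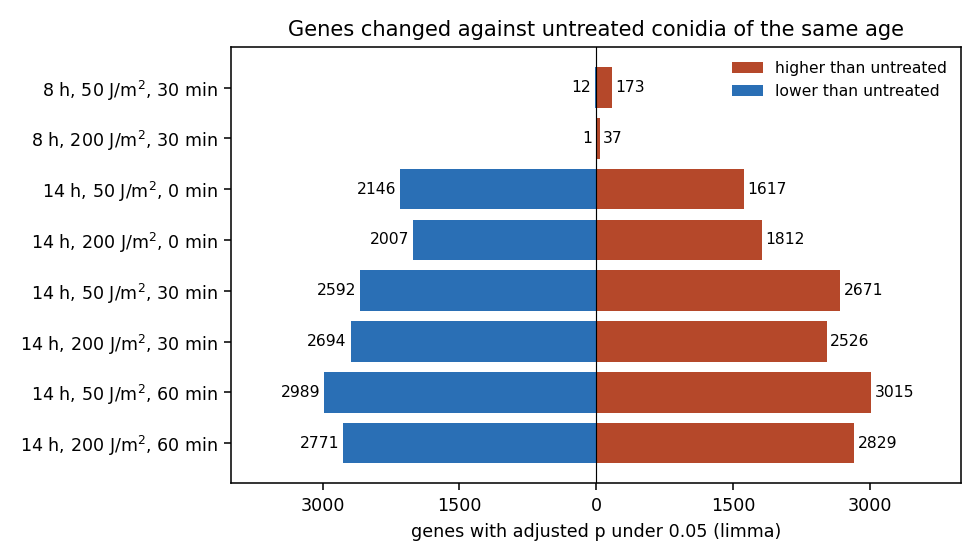
Number of genes higher (right) and lower (left) than in untreated conidia of the same age, per dose and recovery time, with adjusted p under 0.05 in limma. The 8 h comparisons reached 185 and 38 genes and the 14 h comparisons 3763 to 6004 genes.

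After 50 J/m2 and 30 min at 8 h few genes passed the test and most of those rose, DNA repair genes among them. Genes for the Ku proteins, which bind broken DNA ends, and a nucleotide excision repair gene rose, and so did 1 RNA-3′-phosphate cyclase and 1 adenosine deaminase gene. Ribosomal protein genes moved slightly down as a group. Of 5371 genes tested, 173 rose and 12 fell, each at least 2-fold. In simulated data with the depth and spread of these libraries, limma recovered 32.0% of 4-fold rises and 14.0% of 4-fold falls (50 genes each). The strongest rise with a named product was the AAA-ATPase gene TOB3 (FMAN_05568), at 4.57 ± 0.92 (limma, adjusted p = 0.019). The RNA-3′-phosphate cyclase gene FMAN_02740 rose by 4.23 ± 0.62, from 82.4 ± 71.8 to 1208 ± 347 normalized counts (limma, adjusted p = 0.00598). The GNAT acetyltransferase gene FMAN_14044 rose by 3.96 ± 0.36, from 9.38 ± 3.16 to 157 ± 7.96 (limma, adjusted p = 0.00122). Argininosuccinate synthetase (FMAN_05732) rose by 3.94 and the adenosine deaminase AAH1 (FMAN_08241) by 3.90. The largest falls were smaller, namely −1.85 for acetylxylan esterase (FMAN_00700), −1.77 for a class I alpha-mannosidase (FMAN_01492) and −1.62 for the mitochondrial morphology gene mmm1 (FMAN_08012).

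Among 13 nucleotide excision repair genes at this age, 1 rose (4 over the list alone), and the list stood above the other genes (camera, median 0.52, adjusted p = 0.0141 and adjusted p = 0.282 with an estimated correlation, up to 0.0871 without 1 library). Its called member was RAD16 (FMAN_05530), at 2.17 ± 0.50 (limma, adjusted p = 0.0372), while RAD14 (FMAN_00217) reached 1.61 and RAD7 (FMAN_05529) 1.55, with limma adjusted p = 0.0997 and 0.133. In the list of repair genes under other names, 2 rose (5 rising and 1 falling over the list alone, camera, median 0.41, adjusted p = 0.0499 and adjusted p = 0.283 with an estimated correlation, 0.0598 at equal totals, 0.0528 with TMM factors, 0.0698 with a replicate block, up to 0.11 without 1 library). The 2 were Ku70 (FMAN_02829) at 2.51 and Ku80 (FMAN_04818) at 2.17. The cross-link repair gene PSO2 (FMAN_01227) reached 1.42 (limma, adjusted p = 0.0618). The checkpoint kinase gene Chk2 (FMAN_04284) reached 1.63 without passing the test (limma, adjusted p = 0.06). The cyclin pas1 (FMAN_09179) rose by 2.45 and the tRNA ligase FMAN_07760 by 3.16. In the proteasome and ubiquitin list 2 rose (4 over the list alone, camera, median 0.04, adjusted p = 0.29), led by CUE3 (FMAN_05699) at 2.56 and the ubiquitin-like gene FMAN_09293 at 2.47. In the drug transporter list 2 rose (4 over the list alone, camera, median 0.39, adjusted p = 0.0591, down to 0.0314 without 1 library), namely the multidrug resistance gene fnx1 (FMAN_08934) at 3.42 and FMAN_02594 at 2.28. The 59 cytosolic ribosomal protein genes shifted down slightly (camera, median −0.25, adjusted p = 0.0157 and adjusted p = 0.736 with an estimated correlation, up to 0.602 without 1 library), with no single call in limma (0 over the list alone), 0 at an unadjusted p under 0.05 and 0 in edgeR or DESeq2. The cytoskeleton genes shifted down as well (camera, median −0.16, adjusted p = 0.0476 and adjusted p = 0.463 with an estimated correlation, 0.0625 at equal totals, up to 0.256 without 1 library), also with no single call in limma (0 over the list alone), 6 at an unadjusted p under 0.05 and 0 in edgeR or DESeq2. The count of 185 rested on the irradiated libraries, since it was 4, 53 and 97 without irradiated replicates 1, 2 and 3. Of the 21 genes named, 16 lost their call without 1 library, and RAD14, RAD7, PSO2 and Chk2 had no call to lose.

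After 200 J/m2 at 8 h 38 genes passed the test, led by rises of single genes of varied function. The genes for making ribosomes lay lower as a group, while drug transporter genes lay higher. Of 5371 genes, 37 rose and 1 fell, each at least 2-fold. Threonine deaminase ILV1 (FMAN_01676) rose by 3.44 ± 0.62 (limma, adjusted p = 0.0344), the ankyrin gene FMAN_13149 by 3.39 and LDB19 (FMAN_07960) by 3.10. A fatty acid desaturase gene (FMAN_02110) rose by 2.79, the cross-pathway control gene FMAN_03242 by 2.69 and arginase (FMAN_10752) by 2.64. The 52 ribosome biogenesis genes had a lower distribution (camera, median −0.83, adjusted p = 9.56e-06 and adjusted p = 0.602 with an estimated correlation, up to 0.072 without 1 library), again with no single call in limma (0 over the list alone), 10 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2. NOP4 (FMAN_08045) stood at −1.82, PWP2 (FMAN_04129) at −1.79 and UTP18 (FMAN_01095) at −1.63, the last with limma adjusted p = 0.226. The 29 mitochondrial ribosomal protein genes also lay lower (camera, median −0.32, adjusted p = 0.0467 and adjusted p = 0.567 with an estimated correlation, 0.0625 at equal totals, up to 0.29 without 1 library), with no single call in limma (0 over the list alone), 3 at an unadjusted p under 0.05 and 0 in edgeR or DESeq2. Drug transporters lay higher, and 1 rose (4 over the list alone, camera, median 0.54, adjusted p = 0.0377 and adjusted p = 0.386 with an estimated correlation, 0.101 with a replicate block, up to 0.112 without 1 library), the called member being FMAN_02594 at 2.36. The count of 38 depended on single libraries, at 61, 8 and 422 (204 higher, 218 lower) without untreated replicates 1, 2 and 3. In limma it was 0 without irradiated replicate 1 (323 at an unadjusted p under 0.05) and 0 without irradiated replicate 2 (688). Of the 10 genes named, 7 lost their call without 1 library, and the others, NOP4, PWP2 and UTP18, had no call to lose.

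Set directly against each other at 8 h, the doses differed in gene groups in camera, calls that all ended with an estimated correlation. The main limma fit called no single gene. Repair and ribosome biogenesis genes lay lower after 200 than after 50 J/m2, and ribosomal protein, glycolysis and respiration genes higher. In limma 0 of 5371 genes differed (450 at an unadjusted p under 0.05), edgeR called 0 and DESeq2 64 (8 higher, 56 lower). Limma called 42 (4 higher, 38 lower) with only the groups compared, 46 (1 higher, 45 lower) with a replicate block and 9 lower with a pseudocount of 5. The 13 nucleotide excision repair genes had a median difference of −0.92 (camera, adjusted p = 3.56e-06, and adjusted p = 0.178 with an estimated correlation). The largest was RAD16 (FMAN_05530) at −2.74 ± 0.56 (limma, adjusted p = 0.138), and RAD4 (FMAN_02517) stood at −1.50. The 17 repair genes under other names had a median of −0.66 (camera, adjusted p = 0.000206, and adjusted p = 0.196 with an estimated correlation). Ku70 (FMAN_02829) stood at −1.98, Ku80 (FMAN_04818) at −1.65 and RAD13 (FMAN_01369) at −1.44. Base excision and mismatch repair genes were lower (camera, median −0.37, adjusted p = 0.0458 and adjusted p = 0.283 with an estimated correlation, 0.0902 with a replicate block, up to 0.18 without 1 library). Cytosolic ribosomal proteins (camera, median 0.57, adjusted p = 2.59e-07), glycolysis and TCA cycle genes (median 0.58, adjusted p = 0.0377, up to 0.139 without 1 library) and mitochondrial respiration genes (median 0.31, adjusted p = 0.0499, 0.0546 with TMM factors, up to 0.383 without 1 library) were higher and ribosome biogenesis genes lower (median −0.52, adjusted p = 0.00343, up to 0.342 without 1 library). The last 4 calls ended at adjusted p = 0.407 to 0.723 with an estimated correlation, and at adjusted p = 0.132 to 0.62 in fry. Over the list alone limma called 2 excision repair genes and 5 repair genes under other names, all lower, and none in the other 5 lists. Over all genes it called 0 members of the 7 lists, with 7, 6, 1, 2, 2, 0 and 3 at an unadjusted p under 0.05 in the order given, edgeR called 0 and DESeq2 1, an excision repair gene.

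At 14 h, conidia harvested directly after irradiation already differed from untreated conidia in 3763 and 3819 genes after 50 and 200 J/m2. The 3062 called at both doses all moved the same way. Both doses share the untreated libraries. The largest rises with a named product included 4 transporter genes, and the glucose-repressible gene Grg1 was among the largest falls. The DNA repair lists lay lower, homologous recombination without a camera call, and so did DNA replication, proteasome and translation factor genes. Mitochondrial respiration and mitochondrial ribosome genes lay higher at both doses, and cytosolic ribosomal protein genes after 200 J/m2 and, without untreated replicate 3, after 50 J/m2. After 50 J/m2, 1617 of 8947 genes rose and 2146 fell, and after 200 J/m2, 1812 rose and 2007 fell. With each library rescaled to the same total, the medians of all genes shifted by −0.21 and −0.22 and the splits became 1238 higher with 2825 lower and 1328 higher with 2726 lower. A multidrug resistance gene (FMAN_02584) rose by 5.85 ± 0.26 and 5.70 ± 0.26 (limma, adjusted p = 2.1e-12 and 1.01e-11), from 358 ± 159.7 to 19484 ± 589 and 17579 ± 1567. A lysine permease gene (FMAN_05063) rose by 4.59 and 4.21, a monocarboxylate transporter gene (FMAN_01804) by 4.46 and 4.24, and a formate transport gene (FMAN_13964) by 4.19 and 3.74. Grg1 (FMAN_04250) changed by −5.35 ± 0.24 and −5.07 ± 0.24 (limma, adjusted p = 2.7e-12 and 1.01e-11), from 26544 ± 3518 to 648 ± 40.9 and 782 ± 31.1. The drug transporter list went both ways, and 7 rose and 9 fell, then 8 and 11 (8 and 11, then 8 and 12, over the list alone) of 32 (camera, adjusted p = 0.928 and 0.841), the list direction after 50 J/m2 turning at equal totals.

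Of the DNA repair lists, 3 were called lower directly after irradiation. In the nucleotide excision repair list 1 rose and 9 fell, then 1 and 9 (1 and 10, then 1 and 9, over the list alone) of 15 (camera, medians −0.96 and −0.78, adjusted p = 0.0377 and 0.0449, and adjusted p = 0.463 and 0.484 with an estimated correlation, the first up to 0.0996 without 1 library, the second up to 0.111 without 1 library). RAD23 (FMAN_04658) changed by −1.07 and −0.98, and rad2 (FMAN_10553) by −1.60 and −1.29. Among 25 repair genes under other names 1 rose and 17 fell, then 1 and 16 (1 and 18, then 1 and 16, over the list alone, camera, medians −0.86 and −0.89, adjusted p = 0.000269 and 0.000136, and adjusted p = 0.122 and 0.122 with an estimated correlation). These included Ku70 (FMAN_02829) at −2.09 and −2.03, the UV-damaged DNA-binding gene FMAN_02500 at −1.09 and −1.02 and mus-11 (FMAN_07471) at −1.51 and −1.62. In base excision and mismatch repair 8 fell, then 7 (8, then 7, over the list alone) of 15 (camera, medians −0.63 and −0.52, adjusted p = 0.0141 and 0.0104, and adjusted p = 0.275 and 0.259 with an estimated correlation). These included uracil-DNA glycosylase (FMAN_01367) at −2.36 and −2.13 and a mismatch repair gene (FMAN_04294) at −1.65 and −1.75. In homologous recombination 4 fell, then 4 (4, then 4, over the list alone) of 8, which did not pass (camera, medians −0.94 and −0.78, adjusted p = 0.0784 and 0.139). The checkpoint kinase gene RAD53 (FMAN_01147) changed by −1.13 and −1.35, against 2.01 and 1.80 for a DNA damage response gene (FMAN_07792). In that list 1 rose and 6 fell, then 1 and 5 (1 and 7, then 1 and 7, over the list alone, camera, medians −0.63 and −0.59, adjusted p = 0.164 and 0.0826). DNA replication genes were lower, and 14 fell, then 10 (14, then 11, over the list alone) of 19 (camera, medians −0.87 and −0.78, adjusted p = 0.000542 and 0.00134, and adjusted p = 0.304 and 0.335 with an estimated correlation). PCNA (FMAN_00869) changed by −1.85 and −1.51 and a DNA polymerase delta gene (FMAN_04237) by −1.88 and −1.87.

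Protein synthesis and turnover shifted at once as well. In translation factors and tRNA synthetases 3 rose and 37 fell, then 3 and 20 (3 and 38, then 3 and 20, over the list alone) of 57 (camera, medians −0.67 and −0.27, adjusted p = 7.88e-06 and 0.0264, and adjusted p = 0.201 and 0.407 with an estimated correlation, the second up to 0.0675 without 1 library). The tRNA ligase FMAN_07760 stood at −2.64 and −2.19. In proteasome and ubiquitin genes 6 rose and 44 fell, then 6 and 44 (6 and 46, then 6 and 47, over the list alone) of 72 (camera, medians −0.62 and −0.61, adjusted p = 3.73e-05 and 5.88e-06, and adjusted p = 0.283 and 0.27 with an estimated correlation). Mitochondrial ribosomal proteins were higher, and 20 rose and 1 fell, then 26 rose (23 and 1, then 29, over the list alone) of 34 (camera, medians 0.62 and 0.75, adjusted p = 3.56e-06 and 6.76e-08, and adjusted p = 0.449 and 0.395 with an estimated correlation). For mitochondrial respiration 14 rose, then 17 (14, then 19, over the list alone) of 35 (camera, medians 0.24 and 0.39, adjusted p = 0.00183 and 0.000243, and adjusted p = 0.407 and 0.354 with an estimated correlation). Of 62 cytosolic ribosomal proteins 4 rose and 2 fell (0 and 1 over the list alone) after 50 J/m2 and 46 rose (50 over the list alone) after 200 J/m2 (camera, medians −0.05 and 0.71, adjusted p = 0.761 and 5.25e-09, the second adjusted p = 0.458 with an estimated correlation). With 50 J/m2 camera pointed up against the median, turned at equal totals, and called the list upward without untreated replicate 3 (0.0163) or the 2 libraries apart (0.0215). Of 56 ribosome biogenesis genes 1 rose and 5 fell, then 26 and 3 (1 and 4, then 30 and 3, over the list alone, camera, medians −0.13 and 0.64, adjusted p = 0.765 and 0.000246, the second adjusted p = 0.542 with an estimated correlation). The catalase genes CTT1 (FMAN_02267) and FMAN_05008 fell, at −2.23 and −2.21 and at −2.10 and −2.40, and superoxide dismutase (FMAN_01010) changed by −1.53 and −1.39. In the oxidative stress list 4 rose and 8 fell, then 4 and 9 (4 and 8, then 4 and 9, over the list alone) of 25 (camera, adjusted p = 0.406 and 0.246). In secondary metabolism genes 10 rose and 5 fell, then 12 and 6 (11 and 5, then 12 and 6, over the list alone) of 26 (camera, adjusted p = 0.0503 and 0.11, the first 0.0297 at equal totals, 0.0459 with a replicate block, down to 0.0329 without 1 library). The fumonisin regulator ZFR1 (FMAN_05066) rose by 2.15 and 2.20 and the trichothecene gene Tri201 (FMAN_01976) by 2.19 and 2.06. The conidiation gene CON-10 (FMAN_01779) changed by −1.79 and −1.85.

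**Figure D2:**
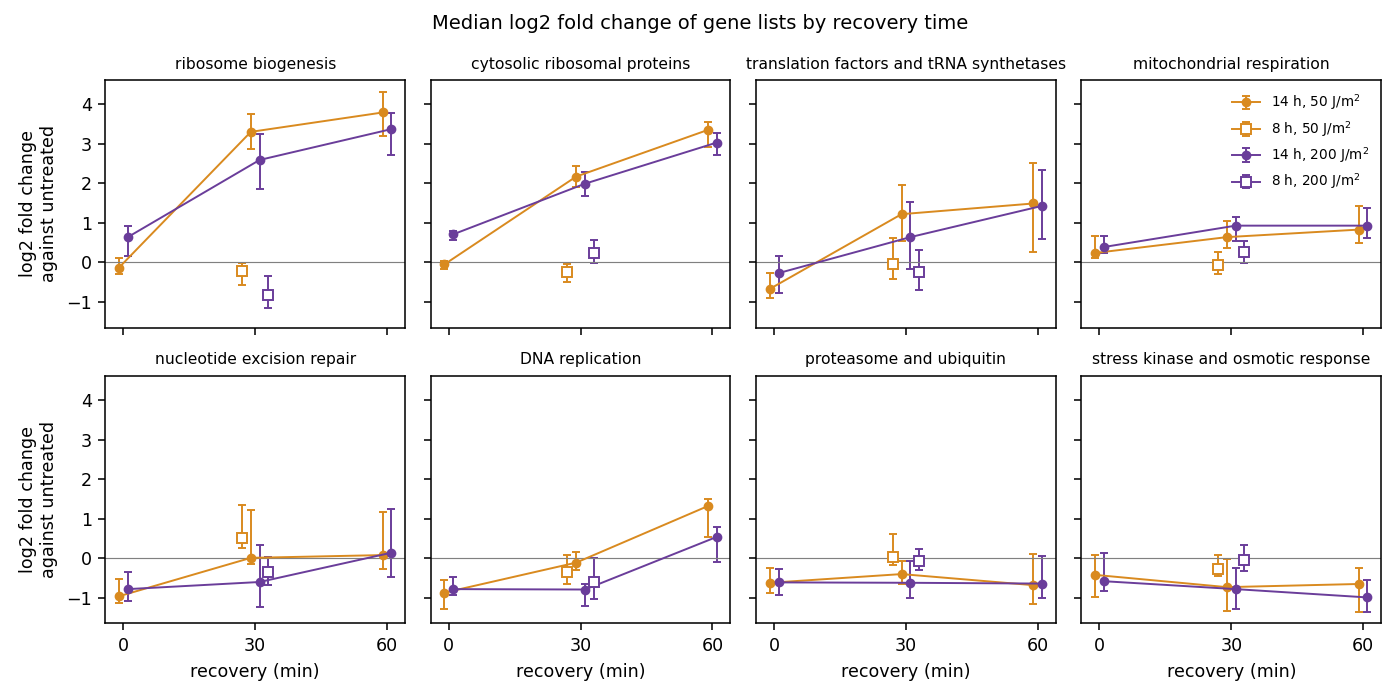
Median log2 fold change against untreated conidia (vertical axis) of 8 gene lists by recovery time in min (horizontal axis), per dose, with bars from the lower to the upper quartile of the genes. Filled points are 14 h and open squares 8 h; the ribosome biogenesis median at 14 h reached 3.79 and 3.37 after 60 min, against −0.83 at 8 h after 200 J/m2 and 30 min.

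After 30 min of recovery at 14 h the genes for building ribosomes had risen strongly at both doses. Ribosomal proteins, RNA polymerase I and III, translation factors and both kinds of mitochondrial list rose with them. Several repair genes now lay above untreated conidia, more of them after 50 than after 200 J/m2. Proteasome, stress kinase and mitosis genes lay lower, and conidium-associated genes lay lower after 50 J/m2. After 50 J/m2, 2671 genes rose and 2592 fell (2476 and 2856 at equal totals). After 200 J/m2, 2526 rose and 2694 fell (2722 and 2478 with TMM factors), and equal totals shifted the median by −0.32 and gave 1982 higher and 3522 lower. A SAM-dependent methyltransferase gene (FMAN_05422) rose by 6.78 ± 0.34 and 5.86 ± 0.34 (limma, adjusted p = 9.92e-12 and 7.23e-11), from 7.96 ± 1.46 to 1100.0 ± 561 and 524 ± 112. TFIIIA (FMAN_04856), which serves 5S rRNA transcription, rose by 6.01 and 4.99. The largest falls were a kinesin gene (FMAN_04258) at −4.50 and −3.33, the ammonium transporter MEAA (FMAN_01053) at −4.15 after 50 J/m2 and ERG-3 (FMAN_13269) at −4.48 after 200 J/m2. Of 56 ribosome biogenesis genes 53 rose and 1 fell, then 52 and 1 (53 and 1, then 52 and 1, over the list alone, camera, medians 3.30 and 2.59, adjusted p = 1.34e-22 and 2.75e-19, and adjusted p = 0.23 and 0.259 with an estimated correlation). All 62 cytosolic ribosomal protein genes rose at both doses, also adjusted over the list alone (camera, medians 2.17 and 1.99, adjusted p = 1.44e-21 and 5.69e-22, and adjusted p = 0.283 and 0.283 with an estimated correlation). In RNA polymerase I and III 9 rose and 1 fell of 10 at both doses, also over the list alone (camera, medians 3.14 and 2.84, adjusted p = 7.16e-05 and 0.000195, and adjusted p = 0.196 and 0.201 with an estimated correlation). In translation factors 42 rose and 4 fell, then 31 and 8 (43 and 4, then 31 and 8, over the list alone, camera, medians 1.22 and 0.64, adjusted p = 7.68e-08 and 0.00519, and adjusted p = 0.178 and 0.345 with an estimated correlation). Mitochondrial ribosomal proteins rose too, 34 rose, then 33 (34, then 33, over the list alone, camera, medians 1.78 and 1.53, adjusted p = 1.36e-12 and 6.95e-12, and adjusted p = 0.29 and 0.305 with an estimated correlation). For respiration 25 rose and 1 fell, then 28 and 1 (25 and 2, then 28 and 1, over the list alone, camera, medians 0.64 and 0.93, adjusted p = 0.00072 and 1.42e-06, and adjusted p = 0.386 and 0.275 with an estimated correlation). Conidium-associated genes moved the other way after 50 J/m2, and 6 fell (6 over the list alone) of 11 (camera, median −0.97, adjusted p = 0.0482 and adjusted p = 0.23 with an estimated correlation, 0.0513 at equal totals, up to 0.0619 without 1 library).

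Repair genes went both ways at 30 min. The RAD4 gene FMAN_01680 rose by 4.21 ± 0.24 after 50 J/m2 and 3.11 ± 0.24 after 200 J/m2 (limma, adjusted p = 3.16e-11 and 2.02e-09), from 37.5 ± 5.55 to 743 ± 264 and 331 ± 32.8. After 50 J/m2, RAD7 (FMAN_05529) rose by 2.65, Ku80 (FMAN_04818) by 2.43 and a mismatch repair gene (FMAN_02614) by 1.98. Other repair genes fell, for instance after 200 J/m2 a second RAD4 gene (FMAN_02517) at −2.09, a RAD16 gene (FMAN_08972) at −1.81 and uracil-DNA glycosylase (FMAN_01367) at −2.79. The excision repair list therefore went both ways, and 6 rose and 3 fell (6 and 3 over the list alone) after 50 and 2 rose and 7 fell (2 and 7 over the list alone) after 200 J/m2 (camera, adjusted p = 0.437 and 0.451). Repair genes under other names were lower after 200 J/m2, and 17 fell (1 rising and 17 falling over the list alone, camera, median −1.08, adjusted p = 0.00235 and adjusted p = 0.178 with an estimated correlation), including the photolyase gene FMAN_04660 at −2.05. After 50 J/m2 4 rose and 7 fell (4 and 7 over the list alone, camera, median −0.09, adjusted p = 0.583), including the photolyase genes FMAN_08744 at −1.56 and FMAN_01648 at −1.83. DNA replication genes were lower after 200 J/m2, and 13 fell (14 over the list alone, camera, median −0.79, adjusted p = 0.00239 and adjusted p = 0.353 with an estimated correlation). Dihydrofolate reductase (FMAN_03081) rose by 2.62 and 2.40, and dUTP pyrophosphatase (FMAN_00867) by 1.17 and 0.80. In cyclins and mitosis 6 rose and 23 fell, then 3 and 24 (6 and 23, then 3 and 23, over the list alone) of 49 (camera, medians −0.60 and −0.73, adjusted p = 0.0255 and 0.00997, and adjusted p = 0.458 and 0.407 with an estimated correlation, the first 0.176 without the 2 libraries apart, up to 0.127 without 1 library, the second 0.0943 without the 2 libraries apart, up to 0.0823 without 1 library). In cytoskeleton and polar growth 9 rose and 29 fell (9 and 29 over the list alone) of 69 after 50 J/m2 (camera, median −0.43, adjusted p = 0.048 and adjusted p = 0.407 with an estimated correlation, 0.052 with TMM factors, 0.0752 without the 2 libraries apart, up to 0.162 without 1 library).

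Proteasome and ubiquitin genes were lower at 30 min, and 8 rose and 30 fell, then 8 and 43 (8 and 29, then 9 and 44, over the list alone, camera, medians −0.40 and −0.62, adjusted p = 0.0199 and 0.00066, and adjusted p = 0.458 and 0.353 with an estimated correlation, the first up to 0.105 without 1 library). Stress kinase genes were lower too, 1 rose and 10 fell, then 1 and 12 (1 and 10, then 1 and 12, over the list alone) of 20 (camera, medians −0.73 and −0.78, adjusted p = 0.0131 and 0.0157, and adjusted p = 0.196 and 0.196 with an estimated correlation). The Ste20-like kinase Don3 (FMAN_04155) stood at −2.54 and −2.09. Among chaperones 22 rose and 10 fell, then 18 and 10 (22 and 10, then 18 and 11, over the list alone) of 40 (camera, adjusted p = 0.125 and 0.282). Catalase-1 (FMAN_05008) was at −3.09 and −3.19 and CTT1 (FMAN_02267) at −2.14 and −2.52. The light-response gene white collar 2 (FMAN_01551) rose by 1.78 and 1.98.

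**Figure D3:**
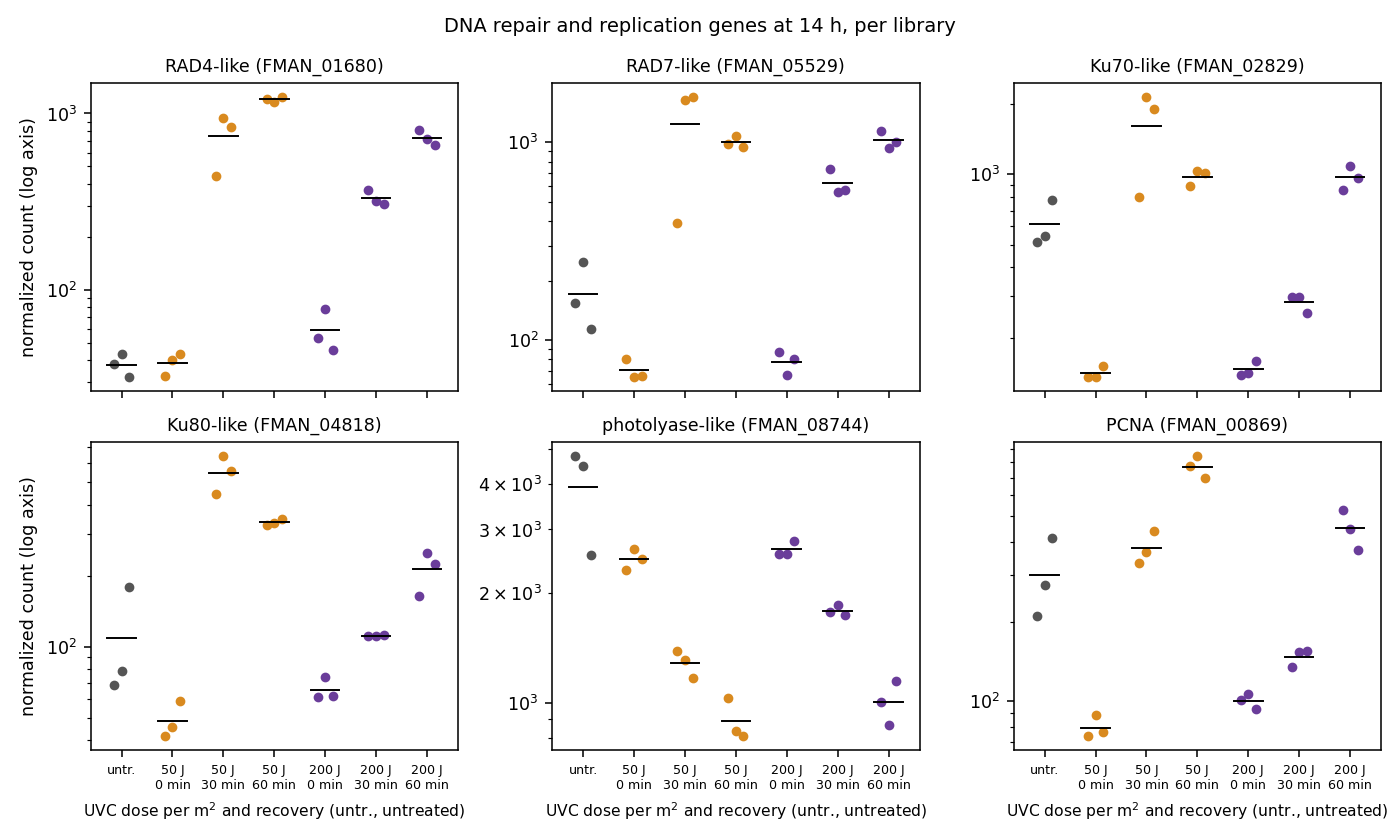
Normalized counts (log axis) of 6 DNA repair and replication genes in each 14 h library (points) and group means (lines), by dose and recovery time. The RAD4 gene FMAN_01680 rose from 37.5 in untreated conidia to group means of 743 after 50 J/m2 and 331 after 200 J/m2 at 30 min.

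By 60 min the rise of the ribosome genes was larger still, and several repair and nucleotide synthesis genes stood above untreated conidia at both doses. DNA replication genes had returned from their early fall, with most now higher after 50 J/m2. Of single genes, 2 photolyase genes and catalase-1 were lower, and the stress kinase list was lower. After 50 J/m2, 3015 genes rose and 2989 fell, and after 200 J/m2, 2829 rose and 2771 fell (2535 and 3117 at equal totals). The enoate reductase gene OYE2 (FMAN_13877) rose by 7.31 ± 0.90 and 5.70 ± 0.90 (limma, adjusted p = 4.76e-07 and 1.56e-05) and the ribosome assembly helicase SPB4 (FMAN_10665) by 6.93 and 5.78. The falls were led by the glucose transporter gene RCO3 (FMAN_08114) at −5.99 and hchA (FMAN_06875) at −5.77 after 50 J/m2, a calcium exchanger gene (FMAN_09304) at −5.68 and −4.52 and Grg1 (FMAN_04250) at −5.55 and −4.38. In ribosome biogenesis 55 rose and 1 fell, then 53 and 1 (55 and 1, then 54 and 1, over the list alone, camera, medians 3.79 and 3.37, adjusted p = 8.16e-21 and 8.13e-21, and adjusted p = 0.243 and 0.243 with an estimated correlation). All 62 cytosolic ribosomal proteins rose at both doses, also adjusted over the list alone (camera, medians 3.35 and 3.03, adjusted p = 3.15e-24 and 5.83e-26, and adjusted p = 0.275 and 0.259 with an estimated correlation). All 34 mitochondrial ribosomal proteins rose as well, also adjusted over the list alone (camera, medians 2.58 and 2.07, adjusted p = 7.28e-14 and 1.55e-13, and adjusted p = 0.283 and 0.283 with an estimated correlation). In RNA polymerase I and III 9 rose, then 9 rose and 1 fell (9, then 9 and 1, over the list alone, camera, adjusted p = 9.83e-05 and 9.38e-05, and adjusted p = 0.196 and 0.196 with an estimated correlation). In translation factors 40 rose and 5 fell, then 43 and 4 (40 and 5, then 43 and 4, over the list alone, camera, adjusted p = 9.47e-07 and 3.85e-08, and adjusted p = 0.196 and 0.178 with an estimated correlation). For respiration 27 rose and 2 fell, then 28 and 2 (27 and 2, then 28 and 2, over the list alone, camera, adjusted p = 0.000193 and 7.88e-06, and adjusted p = 0.35 and 0.283 with an estimated correlation). Among chaperones 22 rose and 9 fell (22 and 9 over the list alone) after 50 J/m2 (camera, median 0.92, adjusted p = 0.0355 and adjusted p = 0.407 with an estimated correlation, 0.0678 without the 2 libraries apart, up to 0.0709 without 1 library).

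At 60 min the RAD4 gene FMAN_01680 stood at 4.98 ± 0.24 and 4.25 ± 0.24 (limma, adjusted p = 1.51e-12 and 2.37e-11), with 1202 ± 37.1 and 729 ± 75.4 normalized counts. RAD7 (FMAN_05529) rose by 2.60 and 2.64, and RAD16 (FMAN_05530) by 2.02 after 50 J/m2, while the RAD16 gene FMAN_08972 was at −2.02 after 200 J/m2. In the excision repair list 7 rose and 2 fell, then 7 and 4 (7 and 2, then 7 and 4, over the list alone, camera, adjusted p = 0.417 and 0.651). In homologous recombination 5 rose, then 2 (5, then 1, over the list alone) of 8 (camera, medians 0.64 and 0.40, adjusted p = 0.25 and 0.677), RAD57 (FMAN_01325) by 1.3 and 0.82. In base excision and mismatch repair 6 rose and 5 fell (6 and 5 over the list alone) after 200 J/m2, a list direction that turned at equal totals (camera, median 0.07, adjusted p = 0.999). In DNA replication 13 rose and 3 fell (13 and 3 over the list alone) after 50 J/m2 (camera, median 1.32, adjusted p = 0.0639, 0.0373 without the 2 libraries apart, down to 0.0301 without 1 library) and 7 rose and 3 fell (6 and 3 over the list alone) after 200 J/m2 (camera, median 0.54, adjusted p = 0.7). PCNA (FMAN_00869) stood at 1.41 after 50 J/m2. Of 5 nucleotide precursor genes 3 rose, then 3 (3, then 3, over the list alone, camera, adjusted p = 0.0929 and 0.138). Dihydrofolate reductase (FMAN_03081) rose by 2.29 and 2.95, dUTP pyrophosphatase (FMAN_00867) by 2.52 and 1.97 and thymidylate synthase CDC21 (FMAN_00890) by 2.09 and 1.1. The photolyase gene FMAN_08744 was at −2.10 and −1.92 and FMAN_01648 at −2.51 and −2.30. DNA polymerase theta (FMAN_04594) rose by 2.38 after 50 J/m2.

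Proteasome and ubiquitin genes remained lower at 60 min, and 9 rose and 43 fell, then 6 and 42 (9 and 43, then 6 and 42, over the list alone, camera, medians −0.68 and −0.64, adjusted p = 0.0026 and 0.00197, and adjusted p = 0.388 and 0.386 with an estimated correlation). Stress kinase genes were lower, 12 fell, then 2 rose and 15 fell (11, then 2 and 16, over the list alone, camera, medians −0.65 and −0.99, adjusted p = 0.0197 and 0.00272, and adjusted p = 0.201 and 0.178 with an estimated correlation). Conidium-associated genes were lower after 50 J/m2, 5 fell (5 over the list alone) of 11 (camera, median −0.80, adjusted p = 0.0262 and adjusted p = 0.201 with an estimated correlation). Cytoskeleton genes were lower after 200 J/m2, 13 rose and 32 fell (13 and 32 over the list alone, camera, median −0.39, adjusted p = 0.0472 and adjusted p = 0.407 with an estimated correlation, 0.159 without the 2 libraries apart, up to 0.161 without 1 library). In secondary metabolism 4 rose and 11 fell, then 3 and 7 (4 and 11, then 3 and 7, over the list alone, camera, adjusted p = 0.152 and 0.208). The bikaverin polyketide synthase gene FMAN_06935 changed by −3.59 and −3.06. Catalase-1 (FMAN_05008) was at −4.17 and −3.43. Within its list 7 rose and 10 fell, then 7 and 10 (7 and 10, then 8 and 10, over the list alone, camera, adjusted p = 0.402 and 0.519). In cell wall genes 9 rose and 18 fell of 49 at both doses, also over the list alone (camera, adjusted p = 0.611 and 0.266). Among autophagy genes 2 rose and 7 fell, then 1 and 5 (2 and 7, then 1 and 5, over the list alone) of 10 (camera, adjusted p = 0.103 and 0.228). Lists with fewer than 4 tested genes (photolyase and cryptochrome, end joining, translesion synthesis, histones) and lists with no member were not tested.

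The dose comparison at 14 h asks how the responses to 200 and 50 J/m2 differed at each time. Directly after irradiation ribosome, translation factor, RNA polymerase I and III, chaperone and mitochondrial ribosome genes were higher as lists after the higher dose. At 30 min repair, replication and ribosome biogenesis genes were lower after 200 J/m2. At 60 min replication genes were still lower, and carotenoid and conidium genes were higher after 200 J/m2. At 0 min limma called 7 genes, all higher, including SRP40 (FMAN_02765) at 1.34, the methyltransferase activator trm-112 (FMAN_04050) at 1.34 and the nucleolar gene NOP4 (FMAN_08045) at 1.24 ± 0.23 (limma, adjusted p = 0.0378). Of 62 ribosomal proteins 1 was higher (51 over the list alone, camera, median 0.76, adjusted p = 2.2e-39 and adjusted p = 0.196 with an estimated correlation). Of 56 ribosome biogenesis genes 1 was higher (33 over the list alone, camera, median 0.78, adjusted p = 3.93e-25 and adjusted p = 0.203 with an estimated correlation). Over the list alone, 13 translation factor, 3 RNA polymerase and 2 chaperone genes were higher (camera, median 0.27, adjusted p = 3e-08, then median 0.33, adjusted p = 0.0223, up to 0.138 without 1 library, then median 0.14, adjusted p = 0.0271, up to 0.13 without 1 library). Mitochondrial ribosomal proteins were slightly higher (camera, median 0.12, adjusted p = 0.0483, up to 0.126 without 1 library). These 4 calls ended at adjusted p = 0.178 to 0.723 with an estimated correlation. The count of 7 was 132 without replicate 1 of the 200 J/m2 group and 0 without its replicate 2 (434 at an unadjusted p under 0.05 in limma) or replicate 1 of the 50 J/m2 group (567). It was 1 without replicate 3 of the 200 J/m2 group, and 3 and 2 without replicates 2 and 3 of the 50 J/m2 group. It was 362 without the 2 libraries apart.

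At 30 min, 802 genes were higher and 1181 lower after 200 than after 50 J/m2, and at equal totals, which shifted the median by −0.20, 499 were higher and 1822 lower. Tryptophan 2,3-dioxygenase (FMAN_03571) was higher by 2.79 ± 0.44 (limma, adjusted p = 0.000274). Dihydrodipicolinate synthase (FMAN_07353) was higher by 2.79 ± 0.19 (limma, adjusted p = 3.99e-08), with 463 ± 44.3 against 68.0 ± 22.1. Among the largest falls was Ku70 (FMAN_02829) at −2.39 ± 0.25 (limma, adjusted p = 6.48e-06), with 284 ± 24.9 against 1617 ± 714, along with the TOB3 genes FMAN_13640 at −2.75 and FMAN_05568 at −2.41. In nucleotide excision repair 9 were lower (11 over the list alone, camera, median −0.88, adjusted p = 9.48e-05), homologous recombination 3 were lower (3 over the list alone) (median −0.60, adjusted p = 0.021, up to 0.0743 without 1 library), base excision and mismatch repair 6 were lower (9 over the list alone) (median −0.54, adjusted p = 0.00591) and repair under other names 7 were lower (9 over the list alone) (median −0.62, adjusted p = 0.000206). ERCC6 (FMAN_08071) stood at −1.38 and RAD4 (FMAN_01680) at −1.10. In DNA replication 10 were lower (13 over the list alone, camera, median −0.80, adjusted p = 7.16e-05), ribosome biogenesis 24 were lower (27 over the list alone) (median −0.56, adjusted p = 5.08e-08) and translation factors 1 was higher and 24 were lower (1 and 26 over the list alone) (median −0.51, adjusted p = 4.68e-08). These and the repair calls ended at adjusted p = 0.122 to 0.407 with an estimated correlation. In respiration 3 were higher (0 over the list alone, camera, median 0.13, adjusted p = 0.016 and adjusted p = 0.485 with an estimated correlation, 0.173 at equal totals, 0.271 without the 2 libraries apart, up to 0.224 without 1 library). In secondary metabolism 5 were higher (5 over the list alone, camera, median 0.30, adjusted p = 0.0492 and adjusted p = 0.353 with an estimated correlation, up to 0.148 without 1 library). The blue-light receptor gene VVD (FMAN_09064) was higher by 1.81. The count of 1983 was 473 with only the groups compared, 1197 without replicate 3 of the 200 J/m2 group and 3322 without the 2 libraries apart.

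At 60 min, 1345 genes were higher and 1091 lower, and at equal totals, which shifted the median by −0.15, 1050 were higher and 1612 lower. A transposase gene (FMAN_08752) was higher by 3.73 ± 0.34 (limma, adjusted p = 5.49e-07), with 114 ± 32.3 against 7.63 ± 2.36, and the pH-response gene palI (FMAN_07479) by 2.53. A cell wall mannoprotein gene (FMAN_02481) was lower, at −2.64 ± 0.18 (limma, adjusted p = 1.88e-08), as was HOC1 (FMAN_08684) at −2.08. In DNA replication 9 were lower (1 higher and 13 lower over the list alone, camera, median −0.72, adjusted p = 0.000375) and repair under other names 7 were lower (7 over the list alone) (median −0.55, adjusted p = 0.00907). MUS-42 (FMAN_00887) stood at −2.04 and DNA polymerase theta (FMAN_04594) at −1.59. In ribosome biogenesis 17 were lower (17 over the list alone, camera, median −0.42, adjusted p = 3.73e-05), mitochondrial ribosomal proteins 5 were lower (0 over the list alone) (median −0.43, adjusted p = 0.000144), and chaperones 3 were higher and 8 were lower (3 and 10 over the list alone) (median −0.31, adjusted p = 0.0455, up to 0.0754 without 1 library), and cytosolic ribosomal proteins were lower as a list (median −0.32, adjusted p = 0.00343). These and the replication and repair calls ended at adjusted p = 0.196 to 0.7 with an estimated correlation. In conidium-associated genes 5 were higher (8 over the list alone, camera, median 0.84, adjusted p = 0.016 and adjusted p = 0.196 with an estimated correlation), with Grg1 (FMAN_04250) at 1.17. In carotenoid and light genes 4 were higher (4 over the list alone) of 5 (camera, median 1.07, adjusted p = 0.0499 and adjusted p = 0.458 with an estimated correlation, 0.0505 without the 2 libraries apart, up to 0.0875 without 1 library), with VVD (FMAN_09064) at 1.07. The count of 2436 was 1525 and 1478 without replicate 3 of the 50 and 200 J/m2 group. It was 3937 without the 2 libraries apart and 4261 with only the groups compared.

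The recovery comparison asks what changed between 0, 30 and 60 min within each dose, where UVC and elapsed time cannot be separated. From 0 to 30 min ribosome genes rose at both doses, and after 50 J/m2 excision repair genes rose as a list and most DNA replication genes singly. From 30 to 60 min DNA replication genes rose at both doses, mitosis genes rose from their lower level of 30 min, and after 200 J/m2 the repair lists rose in that interval. After 50 J/m2, 2670 genes rose and 2381 fell from 0 to 30 min, led by a sugar epimerase gene (FMAN_01349) at 6.19 ± 0.62 (limma, adjusted p = 4.48e-08). The ceramide gene LAG1 (FMAN_13129) changed by −3.76. In nucleotide excision repair 9 rose (9 over the list alone, camera, median 1.03, adjusted p = 0.0242), RAD4 (FMAN_01680) by 4.18 and RAD7 (FMAN_05529) by 3.85. In ribosome biogenesis 54 rose and 1 fell (54 and 1 over the list alone, camera, median 3.49, adjusted p = 8.77e-24) and secondary metabolism 1 rose and 15 fell (1 and 15 over the list alone) (median −0.89, adjusted p = 0.0025). All of them ended at adjusted p = 0.225 to 0.23 with an estimated correlation. Among ribosomal proteins 59 rose (59 over the list alone, camera, adjusted p = 7.78e-21), RNA polymerases 9 rose and 1 fell (9 and 1 over the list alone) (adjusted p = 5.31e-05), translation factors 47 rose and 1 fell (47 and 1 over the list alone) (adjusted p = 1.41e-14), mitochondrial ribosomal proteins 31 rose (31 over the list alone) (adjusted p = 6.69e-07) and chaperones 20 rose and 10 fell (20 and 10 over the list alone) (adjusted p = 0.0404). All these calls ended at adjusted p = 0.122 to 0.45 with an estimated correlation. From 30 to 60 min 1596 rose and 1717 fell (1940 and 1429 at equal totals), the ribosome assembly ATPase midasin (FMAN_04757) by 3.02 and RCO3 (FMAN_08114) by −3.80. In DNA replication 14 rose (16 rising and 1 falling over the list alone, camera, median 1.12, adjusted p = 6.34e-06) and cyclins and mitosis 24 rose and 4 fell (24 and 4 over the list alone) (median 0.63, adjusted p = 0.000188). All of them ended at adjusted p = 0.23 to 0.29 with an estimated correlation. Among ribosomal proteins 53 rose (55 over the list alone, camera, adjusted p = 2.49e-19), ribosome biogenesis genes 18 rose and 1 fell (16 and 1 over the list alone) (adjusted p = 0.000567, 0.1 without the 2 libraries apart, up to 0.102 without 1 library), mitochondrial ribosomal proteins 24 rose and 1 fell (27 and 1 over the list alone) (adjusted p = 1.42e-07) and chaperones 14 rose and 3 fell (18 and 3 over the list alone) (adjusted p = 0.0157). The calls ended at adjusted p = 0.304 to 0.567 with an estimated correlation.

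After 200 J/m2, 1872 genes rose and 1528 fell from 0 to 30 min (1693 and 1776 at equal totals, 2018 and 1287 with TMM factors), TFIIIA (FMAN_04856) by 5.40 ± 0.58 (limma, adjusted p = 4.51e-07). The mitotic activator gene p55CDC (FMAN_01493) changed by −2.88. In ribosome biogenesis 52 rose (52 rising and 1 falling over the list alone, camera, median 1.82, adjusted p = 3.67e-22) and cyclins and mitosis 2 rose and 12 fell (2 and 11 over the list alone) (median −0.44, adjusted p = 0.0223). All of them ended at adjusted p = 0.23 to 0.457 with an estimated correlation. Among ribosomal proteins 57 rose (58 over the list alone, camera, adjusted p = 1.35e-19), RNA polymerases 9 rose and 1 fell (9 and 1 over the list alone) (adjusted p = 1.1e-05), translation factors 35 rose and 1 fell (35 and 1 over the list alone) (adjusted p = 1.55e-10), mitochondrial ribosomal proteins 23 rose (23 over the list alone) (adjusted p = 1.53e-06), respiration 17 rose and 2 fell (17 and 2 over the list alone) (adjusted p = 0.00616) and secondary metabolism 1 rose and 7 fell (1 and 7 over the list alone) (adjusted p = 0.0255, up to 0.0909 without 1 library). The calls ended at adjusted p = 0.122 to 0.449 with an estimated correlation. From 30 to 60 min 1517 rose and 971 fell, and at equal totals, which shifted the median by 0.16, 2042 rose and 614 fell. The p55CDC gene FMAN_01493 rose by 3.47 ± 0.63 in that interval (limma, adjusted p = 0.000825), a methyltransferase gene (FMAN_07222) by 3.54 and arginase (FMAN_00372) by 2.83, and the developmental regulator flbC (FMAN_03113) changed by −1.84. In nucleotide excision repair 8 rose (8 over the list alone, camera, median 0.83, adjusted p = 0.00428), homologous recombination 5 rose (6 over the list alone) (median 0.88, adjusted p = 0.00675), base excision and mismatch repair 9 rose and 1 fell (10 and 1 over the list alone) (median 0.70, adjusted p = 0.00337) and repair under other names 10 rose and 3 fell (13 and 3 over the list alone) (median 0.81, adjusted p = 0.0472, up to 0.0725 without 1 library). Ku70 (FMAN_02829) rose by 1.77. In DNA replication 15 rose (15 over the list alone, camera, median 1.21, adjusted p = 9.35e-08), cyclins and mitosis 16 rose and 2 fell (19 and 2 over the list alone) (median 0.62, adjusted p = 0.0026) and translation factors 36 rose (40 rising and 1 falling over the list alone) (median 0.78, adjusted p = 1.82e-11). These and the repair calls ended at adjusted p = 0.122 to 0.386 with an estimated correlation. Among ribosomal proteins 54 rose (56 over the list alone, camera, adjusted p = 3.04e-19), ribosome biogenesis genes 25 rose (26 over the list alone) (adjusted p = 7.36e-07), mitochondrial ribosomal proteins 12 rose (15 over the list alone) (adjusted p = 0.000108), chaperones 13 rose (14 over the list alone) (adjusted p = 0.0329, up to 0.0534 without 1 library) and secondary metabolism 1 rose and 7 fell (1 and 7 over the list alone) (adjusted p = 0.00283). The calls ended at adjusted p = 0.23 to 0.504 with an estimated correlation. The count of 2488 was 1523 without 30 min replicate 3 and 1548 without 60 min replicate 1, and 4013 without the 2 libraries apart.

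The age comparison asks whether conidia at 14 h responded differently from those at 8 h after 30 min. The response of the ribosome genes was higher at 14 h at both doses, and at 8 h these lists had not risen in camera. Translation factor genes also responded higher at 14 h, and proteasome and conidium-associated genes and Grg1 lower. The fit shares a spread, while the median residual SD was 0.59 at 8 h and 0.36 at 14 h, so p may be too small. With only the groups compared, 1233 and 991 genes were called. In the main fit for 50 J/m2, 1298 genes had the higher response at 14 h and 841 the lower, of 5240 tested. For 200 J/m2 these were 1063 and 888, and at equal totals, which shifted the median by −0.46, 751 and 1425. TFIIIA (FMAN_04856) differed by 6.63 ± 0.92 for 50 J/m2 (limma, adjusted p = 5.89e-06), SPB4 (FMAN_10665) by 6.04 and 5.90 and the SAM-dependent methyltransferase gene FMAN_05422 by 5.46 and 5.65. Lower responses at 14 h included benzoylformate decarboxylase (FMAN_05005) at −4.49 and −6.02 and Grg1 (FMAN_04250) at −3.89 and −4.18. In ribosome biogenesis 49 were higher and 1 was lower, then 49 and 1 (50 and 1, then 50 and 1, over the list alone) of 52, as responses at 14 h against 8 h (camera, medians 3.60 and 3.61, adjusted p = 3.5e-19 and 2e-20, and adjusted p = 0.29 and 0.283 with an estimated correlation). In ribosomal proteins 57 were higher, then 47 (57, then 51, over the list alone) of 59 (camera, medians 2.49 and 1.73, adjusted p = 3.33e-19 and 1.98e-12, and adjusted p = 0.287 and 0.386 with an estimated correlation). RPP0 (FMAN_04600) stood at 3.27 and 2.54. In RNA polymerase I and III 8 were higher, then 7 (8, then 8, over the list alone) of 8 (camera, medians 2.97 and 3.16, adjusted p = 7.3e-05 and 3.73e-05, and adjusted p = 0.243 and 0.23 with an estimated correlation). Among mitochondrial ribosomal proteins 27 were higher, then 24 (28, then 27, over the list alone, camera, medians 2.12 and 1.90, adjusted p = 8.03e-11 and 1.37e-10, and adjusted p = 0.259 and 0.259 with an estimated correlation). In proteasome and ubiquitin 2 were higher and 16 were lower, then 2 and 11 (2 and 14, then 1 and 11, over the list alone) of 53 (camera, medians −0.54 and −0.52, adjusted p = 0.000455 and 0.000449, and adjusted p = 0.201 and 0.201 with an estimated correlation). The ubiquitin-like gene FMAN_09293 stood at −3.05 for 50 J/m2. Among translation factors 26 were higher and 4 were lower, then 22 and 6 (28 and 5, then 23 and 6, over the list alone) of 55 (camera, adjusted p = 0.00281 and 0.0262, and adjusted p = 0.345 and 0.432 with an estimated correlation, the second up to 0.0682 without 1 library). In respiration 4 were higher (1 over the list alone) for 200 J/m2 (camera, median 0.53, adjusted p = 0.0499 and adjusted p = 0.559 with an estimated correlation, 0.182 at equal totals, 0.0546 with TMM factors, 0.148 with a replicate block, 0.105 without the 2 libraries apart, up to 0.312 without 1 library). Among conidium-associated genes 2 were lower, then 2 (2, then 2, over the list alone) of 5 (camera, medians −1.32 and −1.30, adjusted p = 0.0458 and 0.0403, and adjusted p = 0.23 and 0.225 with an estimated correlation, the first 0.0653 without the 2 libraries apart, up to 0.0812 without 1 library, the second up to 0.0872 without 1 library). Each age was a separate set of libraries, so age and library batch cannot be separated.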

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

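Of the tests below, those of a single untreated library, of growth with the dose, of swapped labels and of depth in the 2 libraries that stand apart were chosen after the result was seen. The results listed first drew attention because the response to UVC differed between 8 and 14 h, by a test of the difference itself. It differed in 2139 genes for 50 J/m2 and 1951 genes for 200 J/m2. In 3 of 100 splits of the libraries within each age, the real one included, as many genes differed for 50 J/m2 as the real 2139. The highest other split gave 2426 and was among 8 that kept the true 14 h grouping, and the rest gave at most 688. The count thus follows the 14 h grouping, so the splits do not test the age difference and chance is not excluded. The differences in log2 fold change (14 h less 8 h, limma) were 6.63 for TFIIIA (FMAN_04856, 50 J/m2), 6.04 and 5.90 for SPB4 (FMAN_10665), 5.46 and 5.65 for the methyltransferase gene FMAN_05422, 3.27 and 2.54 for RPP0 (FMAN_04600), −4.49 and −6.02 for benzoylformate decarboxylase (FMAN_05005), −3.89 and −4.18 for Grg1 (FMAN_04250), and −3.05 for the ubiquitin-like gene FMAN_09293 (50 J/m2). By list, the median differences were 3.60 and 3.61 for ribosome biogenesis, 2.49 and 1.73 for ribosomal proteins, 2.97 and 3.16 for RNA polymerase I and III, 2.12 and 1.90 for mitochondrial ribosomal proteins, −0.54 and −0.52 for proteasome and ubiquitin, 1.1 and 0.61 for translation factors, −1.32 and −1.30 for conidium-associated genes and 0.53 for respiration (200 J/m2).

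Far fewer genes changed at 8 h than at 14 h after 30 min. Thinning the 14 h reads to the depth and number of the 8 h libraries left at least 2232 genes changed by 50 J/m2 (2232 to 2273 in 5 draws, against 185 at 8 h), which argues against depth and number alone. Raising the spread as well, from a median residual SD of 0.36 to the 0.59 of 8 h, left at least 1477 (1477 to 1554), which argues against the spread as the whole account. A biological difference between the ages may remain, and a batch of libraries cannot be told apart from it, since each age is its own set.

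Many genes already differed from untreated conidia at 14 h with 0 min of recovery. Leaving out any one untreated library left at least 3366 genes changed by 50 J/m2, which argues against a single library. The median ratio of the 200 to the 50 J/m2 fold change was 0.97 (0.97 to 0.98 over left-out libraries) in 3062 genes changed by both, all in the same direction. Choosing genes changed at both doses leaves out those changed at the higher dose alone, so a change that grows with the dose stays open. The cytosolic ribosomal proteins had a median of 0.71 after 200 J/m2 (camera, adjusted p = 5.25e-09 and adjusted p = 0.458 with an estimated correlation) and −0.05 after 50 J/m2 (adjusted p = 0.761, turned at equal totals, but called upward without untreated replicate 3, 0.0163, or both libraries that stand apart, 0.0215). Because both doses share the untreated libraries, unchanged groups were simulated, and at most 0 genes were called for both in 20 draws. Independent lists would share 327 rises and 481 falls against 1370 and 1692 seen, and the correlation of the fold changes was 0.93 against 0.50 simulated (covariance higher by 1.02). Part of the excess may come from the shared libraries. The slope of the 8 h on the 14 h fold change was 0.09 (0.00 to 0.15 over left-out libraries, 1011 genes). Choosing genes by 14 h changes lowers it, so it argues only against handling, alike at both ages, as the whole change. Handling as a part of it and handling at 14 h alone stay open because no group is described as handled without UVC. So does a fast UVC response that is full at the lower dose.

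At 14 h, untreated replicate 3 and replicate 1 of the 50 J/m2 group at 30 min stood apart from their groups. Mixing of the 2 with each other would give like shares of the other group from genes higher there and genes higher in the own group. The estimates were 0.004 and 0.465 for the untreated library and 0.065 and 0.502 for the other, which argues against it. Swapped labels are argued against by a mean correlation across genes that was higher with the own group by at least 0.110. Lower depth is argued against, as the 2 held up to 6388960 reads against a median of 4394259. Their deviations from their groups correlated across genes with r = 0.468, above the highest of 188 other pairs, 0.360, so a culture or library factor shared by the 2 may be the source, and genes are not independent replicates. No biological explanation was tested.

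For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each, 1 split of the 10, the real one, reached the real count. The real and highest other counts were 185 and 0 for 50 J/m2 at 8 h. Against untreated conidia at 14 h they were 3763 and 0, 5263 and 667, and 6004 and 1 for 50 J/m2 at 0, 30 and 60 min, and 3819 and 1, 5220 and 1, and 5600 and 1 for 200 J/m2. Between the doses they were 7 and 1, 1983 and 28, and 2436 and 0. Between recovery times they were 5051 and 0, and 3313 and 0, after 50 J/m2, and 3400 and 0, and 2488 and 0, after 200 J/m2.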

How the results depend on the processing

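All alternatives were planned except leaving out both libraries that stand apart. No named gene reversed its direction. Of the lists, 3 without a call did (camera, adjusted p). Base excision and mismatch repair (200 J/m2, 60 min) turned at equal totals (0.985) and without untreated replicate 2 (0.93) or irradiated replicate 1 (0.944) or 3 (0.987), but not without untreated replicate 1 (0.996). Ribosomal proteins (50 J/m2, 0 min) turned at equal totals (0.912), in fry (0.931) and without untreated replicate 1 (0.74) or 2 (0.597). They did not turn without irradiated replicate 1 (0.921) or untreated replicate 3, where they were called (0.0163). Drug transporters (50 J/m2, 0 min) turned at equal totals (0.975). The cause of the moves was not tested. Of 203 named gene results, 203 kept direction and call with a pseudocount of 0.5, 202 with 5, 200 without the filter, 200 at equal totals and 202 with TMM factors. With only the groups compared 189 did, in edgeR all but 2 and in DESeq2 199. Of 181 list results, 171 were kept at equal totals, 177 with TMM factors, 139 in fry and 36 with an estimated correlation, where 145 calls ended. Over all 463 list tests camera then called 0 against 145, and fry, which asks another question, 273. With the replicate number as a block 176 were kept and 4 calls ended, and without both libraries that stand apart, of the results it touches, 153 and 10. The genes changed by 200 against 50 J/m2 at 0 min (7) became 3 with a pseudocount of 5, 12 (11 higher) without the filter, 39 at equal totals and 17 with TMM factors. They were 160 (121 higher, 39 lower) with only the groups compared, 2 in edgeR, 169 (164 higher, 5 lower) in DESeq2 and 362 without both libraries that stand apart. The dose comparison at 8 h (0) gave 9 lower with a pseudocount of 5, 42 (4 higher, 38 lower) with only the groups compared and 64 in DESeq2. With only the groups compared, limma called 0 genes for 200 J/m2 at 8 h (519 at an unadjusted p under 0.05), 473 and 4261 between the doses at 30 and 60 min, and 1233 and 991 for the age differences. DESeq2 called 301 and 157 genes for 50 and 200 J/m2 at 8 h. Without both libraries that stand apart, the doses differed in 3322 and 3937 genes at 30 and 60 min and 200 J/m2 changed 4013 from 30 to 60 min. Equal totals shifted the median of all genes by 0.14 for 200 J/m2 at 8 h, 0.13 between the doses at 8 h, −0.12 and −0.15 for 50 J/m2 at 30 min and 200 J/m2 at 60 min, 0.11 from 30 to 60 min after 50 J/m2 and −0.12 for the 50 J/m2 age difference. The medians of the age differences moved by −0.24 and −0.17 without the filter, −0.13 and −0.12 in DESeq2 and, for 200 J/m2, −0.14 in edgeR. The other count alternatives stayed within 1.5 times.

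Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated above 0.1 in 4 of 7 pairs at 8 h (−0.323 to 0.3, own number highest in 4) and in 6 of 63 at 14 h (−0.388 to 0.36, own number highest in 24). With the replicate number as a block, 46 genes (1 higher, 45 lower) differed between the doses at 8 h and 13 between the doses at 0 min, and every other count stayed within 1.5 times.

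Leaving out one library gave 4 to 231 genes for 50 J/m2 and 0 to 422 for 200 J/m2 at 8 h, and 0 between the doses (DESeq2 64, 450 at an unadjusted p under 0.05 with all libraries in limma). At 14 h it gave 3117 to 3602, 4710 to 5673 and 5579 to 6093 for 50 J/m2 at 0, 30 and 60 min, 3100 to 3550, 4682 to 4986 and 5162 to 5511 for 200 J/m2, and 0 to 132, 1197 to 2391 and 1478 to 1994 between the doses. Between times it gave 4508 to 5214 and 2487 to 3098 after 50 J/m2 and 2846 to 3071 and 1523 to 2147 after 200 J/m2, for the ages 1821 to 2485 and 1617 to 2408, and 132 to 149 list calls. A group of 2 that loses a library has 1, which is assumed to vary like the others. Of the named results, 23 of 36 genes and 11 of 16 lists at 8 h, 6 of 155 genes and 22 of 150 lists at 14 h and 0 of 12 genes and 4 of 15 lists between ages lost their call without one library.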

Other observations

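The test of a slower course below was planned before its result was seen, and the genes of the 2 libraries that stand apart were chosen after their values were seen. At 14 h the ABC transporter gene FMAN_00524 lay lower at each later time, at −1.33, −2.52 and −3.30 after 50 J/m2 and at −1.49, −2.31 and −2.95 after 200 J/m2 (limma against untreated conidia). The multidrug transporter gene FMAN_13590 rose by 3.47 and 4.62 at 30 min. The beta-carotene dioxygenase gene FMAN_08103, for retinal synthesis, stood at −2.33 after 50 J/m2 and −1.13 after 200 J/m2 at 60 min. The clock gene FRQ (FMAN_05684) rose by 0.88 and 0.68 at 0 min.

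The genes below were picked by their values out of 601 and 513 at least 4-fold away in the 2 libraries that stand apart, and no gene list was tested there. In untreated replicate 3 the iron permease gene FMAN_09497 had 1.2 normalized counts against a mean of 176.5 in the other 2 libraries, and in replicate 1 of the 50 J/m2 group at 30 min 2.6 against 59. The ferroxidase gene FMAN_09496 had 14.7 against 474.8 and 23.9 against 254, flavohemoglobin (FMAN_13090) 5.3 against 83.1 and 6 against 143.1, and the proton pump PMA1 (FMAN_08843) 11.8 against 192 and 8.5 against 214.9. Aldehyde dehydrogenase (FMAN_01453) was higher in both, with 15913.3 against 1591.9 and 3218.1 against 300.7.

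From 0 to 30 min at 14 h fewer genes changed after 200 than after 50 J/m2 (3400 against 5051), and a candidate explanation is a slower course after the higher dose. Across the 5051 genes that changed from 0 to 30 min after 50 J/m2, the slope of the 200 on the 50 J/m2 change was 0.59 from 0 to 30 min (0.57 to 0.62 over left-out libraries) and 0.72 from 0 to 60 min (0.70 to 0.73). The slope rose by 0.12 (0.10 to 0.14). The genes were chosen for their 0 to 30 min change after 50 J/m2, which lowers the first slope more than the second, so part of the rise is built in and the test decides nothing. A slower course and a smaller change at the higher dose cannot be told apart here.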
